A study of Mus musculus with 2 samples.

How the data were processed

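The series compared single-cell RNA from the ileum of wild-type mice (WT) and of mice heterozygous for the TnfDARE allele, with 1 library per genotype. Per the labels' protocols, libraries were made with a 10x Genomics 3' kit (v3.1) and sequenced on a DNBSEQ-G400. Per the submitters' processing notes, reads were aligned to mm10 and counted with Cell Ranger 7.0.1. The deposited files were 2 Cell Ranger matrices, 3 compartment tables and 1 table with the library, annotation and cell type of each cell. The unit of every deposited matrix was the count, UMIs per gene and cell per the file headers, and all values were whole numbers. The compartment tables held the same counts as the matrices (0 entries differed) for 40967 annotated cells and 32285 genes. How the submitters chose cells, treated doublets and made the annotation was not stated. Annotated cells had at least 801 genes and at most 4.998% mitochondrial UMIs. The WT matrix held 43119 barcodes and 392653380 UMIs, and the TnfDARE matrix 25771 barcodes and 278847306 UMIs.

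All annotated cells entered the main results. The 37 deposited annotations were grouped in 10 classes, and UMIs were summed over the cells of a class in each library and scaled to 1e6 (CPM). Ratios are TnfDARE over WT. Those of CPM have exact 95% conditional binomial intervals, and shares have exact Clopper-Pearson intervals. For ratios of shares, the Clopper-Pearson limits of TnfDARE were divided by the opposite limits of WT, so these bounds are wider than 95% intervals. A gene was called at least 2-fold higher or lower where its ratio passed 2 either way and the interval left out 1. Where a library had 0 UMIs a floor of 3 counts gave the smallest fold. No test between genotypes was made, since cells of 1 library are not replicates. Numbers of genes past the 2-fold call and percentiles among random lists describe these 2 libraries only.

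Genes to be named were fixed by a rule. Among genes with at least 50 UMIs in both libraries together and at least 20 CPM in one, the 12 highest and 12 lowest log2 ratios with 5 CPM added were named in fibroblasts, 6 and 6 in the other classes, and 5 and 5 in each fibroblast type with at least 50 cells per library. Variable segments of immunoglobulin and T cell receptor genes, sex-linked, mitochondrial, haemoglobin and predicted genes, and markers of another compartment were left out of this ranking. Tnf, Tnfrsf1a and Tnfrsf1b were always named. The comparison within FRC1, FRC2 and FDCs_MRCs asked for by the rule was left out, since nearly all their WT cells had barcodes of TnfDARE cells. The 30 gene lists were written from general knowledge, members needed 20 UMIs to be measured, up to 4 were named, and the median log2 ratio of each list was placed among 10000 random lists matched on CPM in 20 bins. The rule, lists, classes and most of the other settings tried were set before the data were examined.

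A gene below 5% of its CPM in the highest class was taken as not told apart from RNA of other cells. For shares of cells with a Tnf UMI, every cell was thinned to 1000 UMIs, which left out 0 cells in the classes used. No doublet caller was run, and cells over 3 times the median UMIs of their annotated type in their library were left out as an alternative. Shared barcodes, those in both libraries with under 0.2 times the UMIs in WT, were left out of WT in an alternative added after the data were seen. In Poisson counts simulated from the pooled profile of a class, planted folds were recovered for 96% to 100% of fibroblast genes and 64% to 100% of granulocyte genes. The intervals held the planted fold for 95.3% to 96.4% of genes. Since the intervals assume such counts, this checked the code only, with no spread between cells or animals. Work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, with gene positions from GENCODE vM21 (GRCm38).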

Results

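Single-cell RNA counts from the mouse ileum were compared between 1 wild-type library (WT) and 1 library from TnfDARE/+ mice, whose Tnf gene lacks an AU-rich element in its 3' untranslated region, at 12 weeks of age. Per the labels' protocols, epithelium was taken off, the remaining tissue was digested, and myeloid (CD45+ with CD11B or CD11C), lymphoid (CD45+ without both) and stromal (CD45- EPCAM1-) cells were sorted and mixed before capture. The question was how stromal and immune cells, fibroblast subtypes above all, differed between healthy ileum and ileum with excess TNF. The deposited annotation covered 22189 WT cells with a median of 8264 UMIs (unique molecular identifiers) and 2687 genes, and 18778 TnfDARE cells with a median of 7156 UMIs and 2459 genes, in 37 cell types. Levels are CPM, counts summed over the cells of a group and scaled to 1e6 UMIs. With 1 library per genotype no value had a replicate check. Intervals beside levels, shares and CPM ratios are exact 95% Poisson, Clopper-Pearson and conditional binomial intervals. Ratios of shares have wider bounds, Clopper-Pearson limits divided by the opposite limits. All of these cover counting error only. Gene positions are those of GENCODE vM21 on GRCm38.

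Libraries shared barcodes, and the sex-linked genes differed between them. Of the WT barcodes, 12203 also occurred in the TnfDARE library and held under 0.2 times as many UMIs in WT, with a median ratio of 0.0654 over all barcodes in both. These included 1660 annotated WT cells (7.48%), spread unevenly over cell types: without them 1 of 208 FRC1 cells, 24 of 189 FRC2 cells, 0 of 119 FDCs_MRCs, 9 of 258 activated macrophages and 170 of 421 resident macrophages were left in WT. Values "without shared barcodes" leave these cells out, a choice made after the data were seen, and no genotype comparison of expression is given for FRC1, FRC2 or FDCs_MRCs. Xist (chromosome X, 103460366 to 103483254, minus strand), the RNA that coats the inactive X chromosome, was detected in 91.3% of WT cells (96.3% without shared barcodes) and in 36.7% of TnfDARE cells. A Y-linked UMI was found in 2.25% of WT cells (0.648% without shared barcodes) and in 51.6% of TnfDARE cells. In fibroblasts the sex-linked list had 4 of 6 measured members at least 2-fold higher in TnfDARE and 2 lower, with Ddx3y at 1.15 CPM in WT and 47.7 CPM in TnfDARE and Xist at 975 and 308 CPM.

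**Figure D1:**
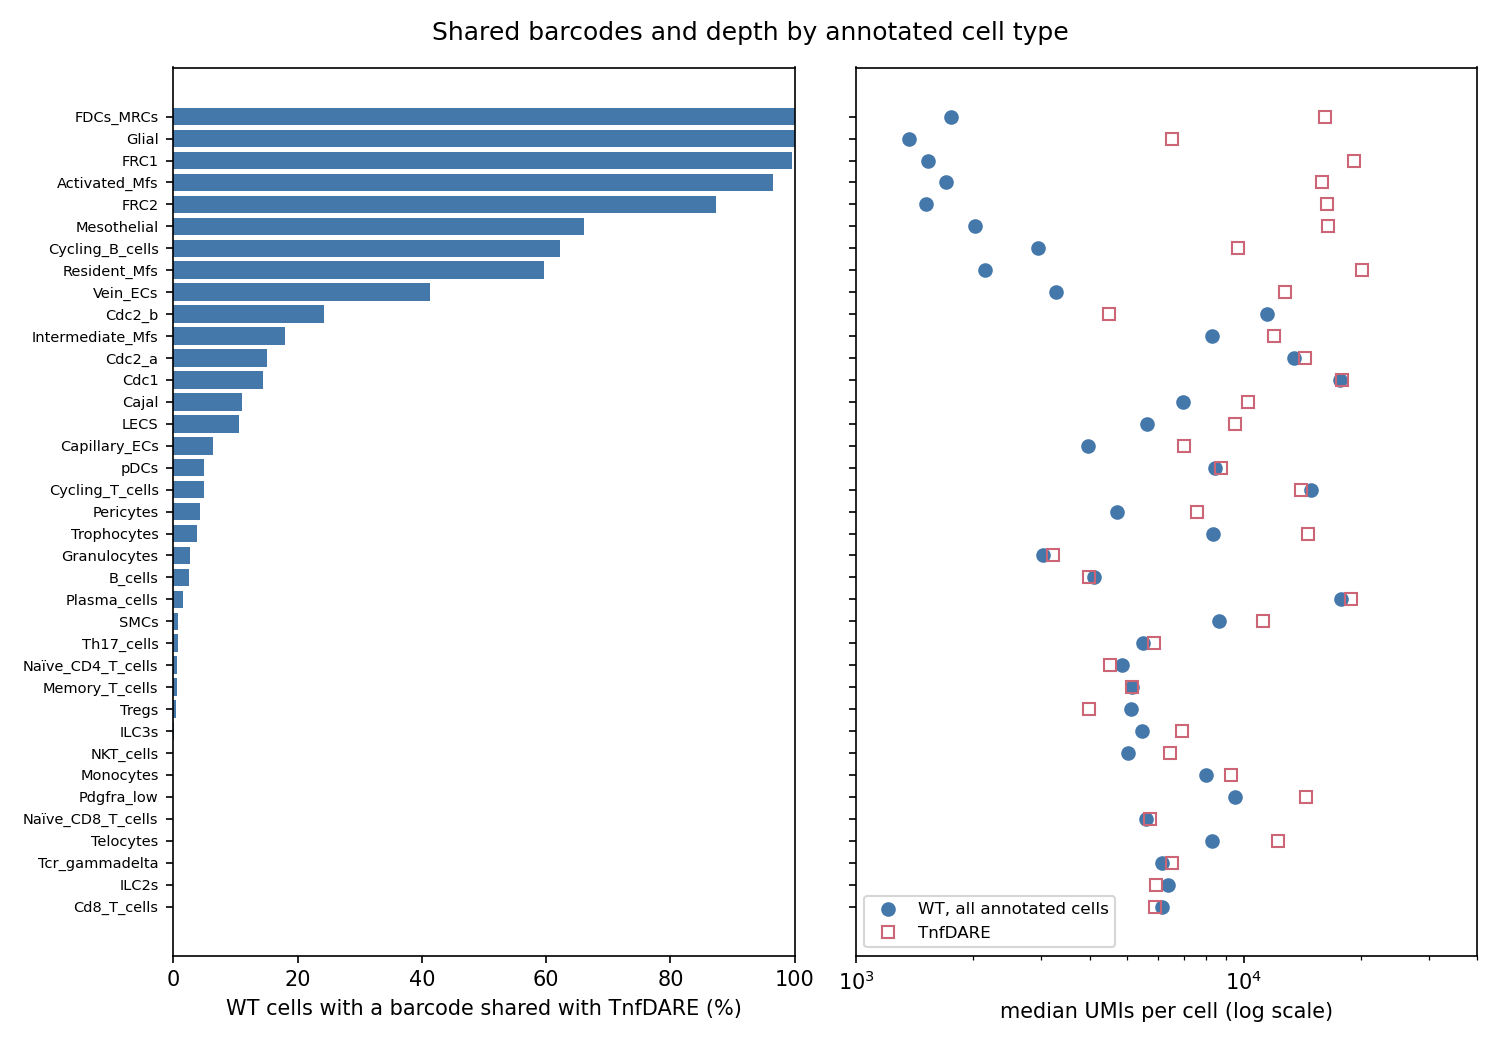
Left, percent of annotated WT cells of each cell type whose barcode also occurred in the TnfDARE library with under 0.2 times the UMIs in WT; right, median UMIs per cell (log scale) of each cell type in WT and TnfDARE, 1 library each. The 119 WT cells annotated FDCs_MRCs were all shared barcodes, and 0 of the 4329 Pdgfra_low cells were.

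How the cell types of each annotated compartment shifted with the genotype was asked first. In the stromal compartment, Pdgfra_low fibroblasts, trophocytes, telocytes and smooth muscle cells took smaller shares in TnfDARE, and fibroblastic reticular cells, lymphatic endothelium, pericytes and glial cells larger ones. In the myeloid compartment granulocytes took a larger share and conventional dendritic cells of the Cdc1 and Cdc2_a types smaller ones, of which only Cdc1 was also a smaller share of all annotated cells. In the lymphoid compartment B cells and regulatory T cells took larger shares, and plasma cells, ILC2s and gamma delta T cells smaller ones. Shares are of the cells that the deposited annotation places in 1 compartment, since sorted myeloid, lymphoid and stromal cells were mixed to set proportions per the labels' protocols, which give stroma as under 10% of all cells in TnfDARE as the ground for sorting. Stromal cells were 40.1% of the annotated cells in WT and 22.9% in TnfDARE.

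Pdgfra_low fibroblasts made up 48.7% of WT stromal cells (4329 cells) and 10.5% of TnfDARE stromal cells (453 cells), a ratio of 0.216 (interval 0.194 to 0.241). Telocytes, fibroblasts under the epithelium that make BMP and Wnt ligands, went from 10.0% to 3.14%, and trophocytes, deeper fibroblasts that make Wnt enhancers and the BMP blocker gremlin, from 16.4% to 9.13%. Smooth muscle cells went from 7.50% to 2.69%. FRC2 cells, fibroblastic reticular cells of the kind that organise lymphoid tissue, were 2.12% in WT and 10.3% in TnfDARE, a ratio of 4.85 (3.85 to 6.14) that became 35.2 without shared barcodes. FRC1 cells were 2.34% and 8.13%, a ratio of 3.48 that became 667 (interval 108 to 29111) with 1 WT cell left. FDCs_MRCs, follicular dendritic and marginal reticular cells, were 1.34% and 5.53%, a ratio of 4.13 (3.04 to 5.64), and 0 WT cells were left without shared barcodes. Lymphatic endothelial cells were 4.88% and 28.3%, a ratio of 5.80 (5.04 to 6.69). Pericytes had a ratio of 4.48, capillary endothelial cells 2.20 and vein endothelial cells 3.21 (5.04 without shared barcodes). Glial cells numbered 1 in WT and 124 in TnfDARE, a ratio of 256 (38.4 to 12033), with 0 WT cells left without shared barcodes. Interstitial cells of Cajal, the pacemakers of gut muscle, had a ratio of 2.84 and mesothelial cells 2.52 (6.86 without shared barcodes).

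Granulocytes were 8.12% of WT and 39.8% of TnfDARE myeloid cells, a ratio of 4.90 (4.14 to 5.85) that was 3.47 without shared barcodes. Activated macrophages were 11.6% and 13.9%, a ratio of 1.20 that became 23.6 (11.7 to 54.8) without shared barcodes. Resident macrophages had a ratio of 0.408 (0.695 without shared barcodes) and monocytes 0.611. Cdc1 cells, which cross-present antigen to CD8 T cells, went from 11.8% to 2.12%, and Cdc2_a cells from 20.9% to 6.94%, while Cdc2_b cells went from 1.66% to 5.04%. The macrophage and monocyte class as a whole went from 54.8% to 44.8%, but from 42.5% without shared barcodes, so its direction turned. As shares of all annotated cells resident macrophages, the macrophage class and the dendritic class were higher in TnfDARE, with ratios of 1.36, 2.71 and 1.38. Cdc2_a cells (2.10% and 2.32% of all annotated cells), monocytes (0.690% and 1.40%) and pDCs (0.270% and 0.415%) turned too.

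B cells were 11.05% of WT and 47.3% of TnfDARE lymphoid cells, a ratio of 4.28 (3.97 to 4.62), and cycling B cells had a ratio of 2.69 (6.96 without shared barcodes). Plasma cells went from 43.2% to 13.9%, a ratio of 0.322 (0.298 to 0.347). ILC2s, innate lymphocytes that make type 2 cytokines, numbered 848 in WT and 44 in TnfDARE, 7.67% and 0.536% of the compartment, a share 14.3-fold lower. Gamma delta T cells were 8.23-fold lower and ILC3s 3.27-fold lower. Regulatory T cells went from 1.96% to 6.04%, a ratio of 3.08 (2.47 to 3.85), and naive CD4 T cells had a ratio of 2.18, while memory T cells (1.05) and Th17 cells (1.07) had ratios whose intervals held 1.

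**Figure D2:**
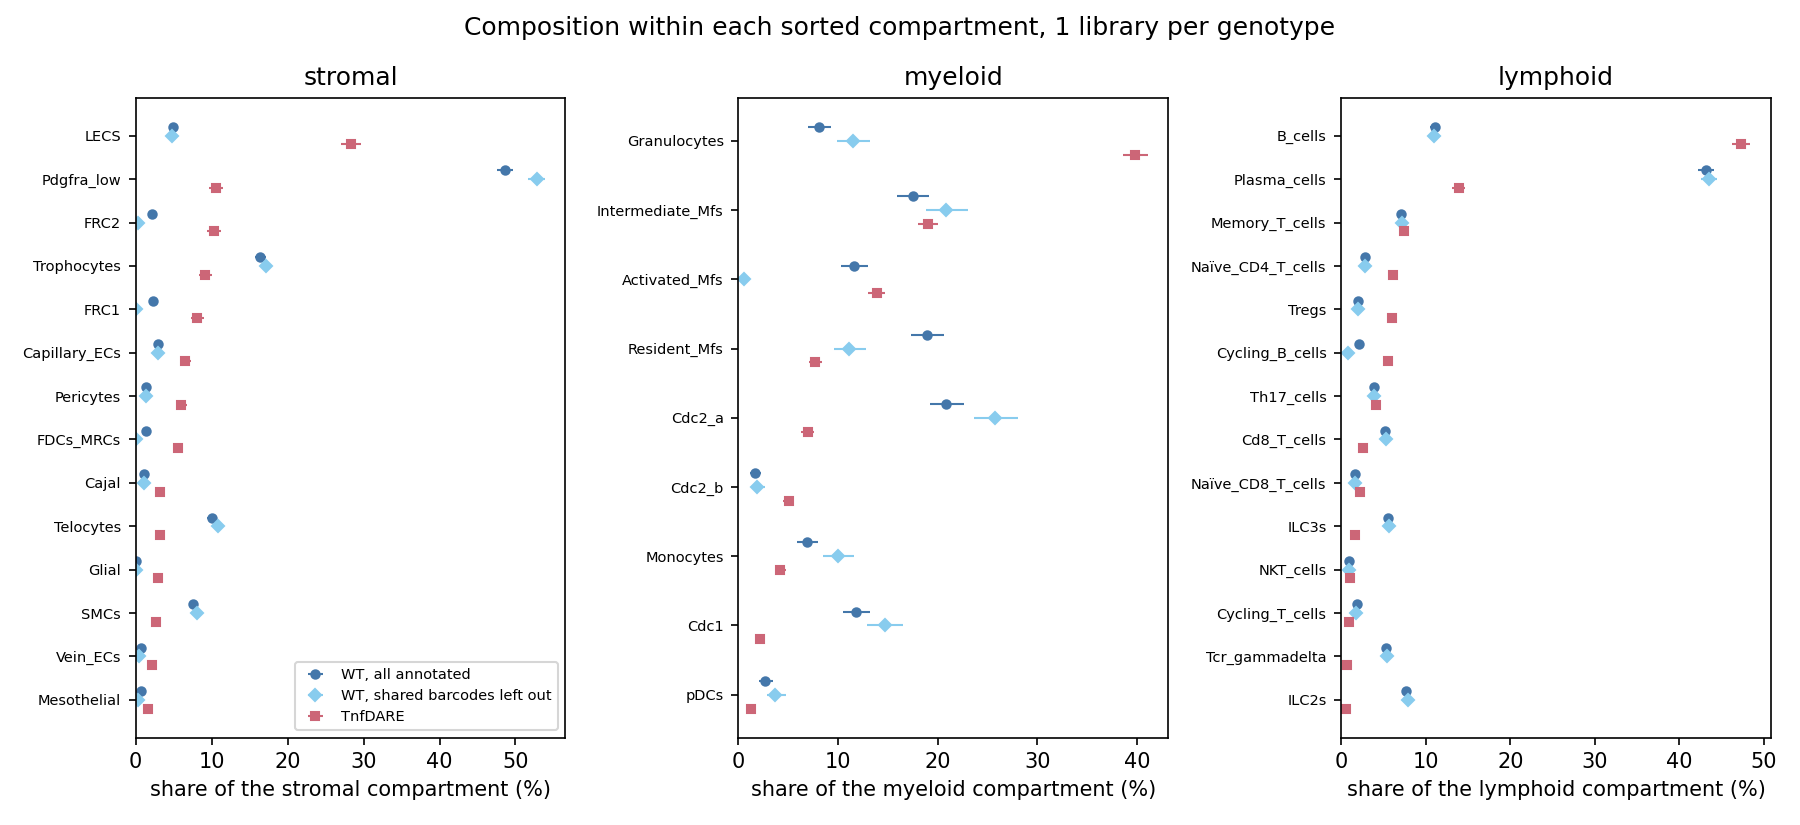
Share of each cell type in its annotated compartment (percent) for all WT cells, WT cells without shared barcodes, and TnfDARE cells, 1 library each, with exact 95% Clopper-Pearson bars. Pdgfra_low cells were 48.7% of stroma in WT and 10.5% in TnfDARE, and B cells were 11.05% and 47.3% of the lymphoid compartment.

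Which cells held Tnf mRNA, and whether the mutant library held more of it, was asked next. Summed over all annotated cells Tnf was higher in TnfDARE, in a library with a larger share of myeloid cells. Granulocytes had the highest Tnf level in both libraries, and within granulocytes, intermediate macrophages and ILC3s the level was lower in TnfDARE. Tnf (ENSMUSG00000024401, chromosome 17, 35199381 to 35202007, minus strand) encodes the cytokine TNF and had 4134 UMIs in WT and 11544 in TnfDARE, 18.0 CPM (17.5 to 18.6) and 64.1 CPM (62.9 to 65.3). This summed level moves with how the sorts were mixed: myeloid cells were 10.04% of WT and 33.4% of TnfDARE annotated cells, and granulocytes held 6522 of the TnfDARE Tnf UMIs. In granulocytes it was 1306 CPM and 766 CPM, a ratio of 0.587 (0.545 to 0.633). Macrophages and monocytes had 104 and 83.7 CPM, a ratio of 0.802 (0.743 to 0.867). Among lymphocytes ILC3s had 129 and 96.4 CPM, 0.745 (0.591 to 0.932), and gamma delta T cells 115 and 79.8 CPM, 0.695 (0.460 to 1.01). Among macrophage types intermediate macrophages had a ratio of 0.521 (0.463 to 0.588) and activated macrophages 0.952 (0.760 to 1.21), which was 0.422 (0.306 to 0.598) without shared barcodes, with 9 WT cells left. The T and innate lymphoid class (50.3 and 25.5 CPM, in a class with smaller shares of ILC3s and gamma delta T cells), the dendritic class (40.6 and 36.1 CPM), the B class (9.33 and 14.7 CPM) and fibroblasts (2.82 and 3.89 CPM) stood below 5% of the granulocyte level in 1 or both libraries. By the 5% rule their Tnf was not told apart from RNA of other cells. Plasma cells, taken as a type that should lack Tnf, held 2.37 and 5.18 CPM. With cells thinned to equal depth, a Tnf UMI was seen in 4.32% of WT and 2.27% of TnfDARE T and innate lymphoid cells. Dendritic cells had one in 3.88% and 3.64%, and plasma cells in 0.23% and 0.44%. In the T and innate lymphoid and dendritic classes this argues against RNA of other cells at the plasma cell level as the whole source. For the B class and fibroblasts the source stays open.

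A Tnf UMI was seen in 70.7% of WT and 59.98% of TnfDARE granulocytes of the myeloid compartment, at median depths of 3040.0 and 3225.5 UMIs. Macrophages and monocytes had one in 26.5% and 40.8% of cells at median depths of 3840.5 and 13662.5 UMIs. With every cell thinned to 1000 UMIs the values were 7.77% and 7.13%, so the direction turned. The WT values include the shared barcodes, without which 652 of 1222 WT cells were left, so the turn cannot be laid to depth alone. Plasma cells, taken as a type that should lack Tnf, had a Tnf UMI in 3.27% and 5.18% at median depths of 17767 and 18848.5 UMIs. Tnfrsf1a (chromosome 6, 125349362 to 125362484, plus strand), the receptor TNFR1, was at 97.5 CPM in WT fibroblasts and 75.7 CPM in TnfDARE fibroblasts, a ratio of 0.777 (0.741 to 0.814), and at 176 and 238 CPM in granulocytes. Tnfrsf1b (chromosome 4, 145213463 to 145246870, minus strand), the receptor TNFR2, was at 26.3 and 36.8 CPM in fibroblasts and at 147 and 195 CPM in macrophages and monocytes. Gene-level counts gave no check of the deleted element itself, and no reads were examined.

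What distinguished TnfDARE from WT fibroblasts was the central question of the series. Acute-phase and antimicrobial genes (Saa3, Hp, Lcn2), neutrophil and lymphocyte chemokines (Cxcl5, Ccl19, Cxcl13) and 14 of 27 NF-kB target genes were higher in TnfDARE fibroblasts. Fbln1, Clec3b, the Wnt genes Dkk2 and Wnt4, the retinoid genes Rbp4 and Lrat and most immediate early genes were lower. Members of both sets differed in these directions within Pdgfra_low cells, trophocytes and telocytes taken singly. The class held 7199 WT cells with a median of 8855 UMIs and 2013 TnfDARE cells with a median of 15953 UMIs.

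Saa3 (chromosome 7, 46711998 to 46715700, minus strand), an acute-phase serum amyloid, was at 465 CPM in WT and 25410.3 CPM in TnfDARE fibroblasts, a ratio of 54.6 (54.0 to 55.3), and 241 against the 106 CPM of WT without shared barcodes. Clu (chromosome 14, 65968483 to 65981547, plus strand), the chaperone clusterin, went from 82.7 to 4274 CPM (51.7-fold, 386-fold without shared barcodes). The haemoglobin-binding Hp (chromosome 8, 109575128 to 109579172, minus strand) went from 52.4 to 2752 CPM, 52.5-fold (1289.7-fold against the 2.13 CPM of WT without shared barcodes). Cxcl5 (chromosome 5, 90759360 to 90761624, plus strand), which attracts neutrophils, went from 85.1 to 3819.8 CPM (44.9-fold, interval 43.7 to 46.1, and 92.0-fold without shared barcodes), and Lcn2, an iron-withholding antimicrobial protein, from 13.2 to 680.0 CPM (51.7-fold, 307-fold without shared barcodes). Ccl19 (chromosome 4, 42754525 to 42756577, minus strand), a ligand of the T cell homing receptor CCR7, went from 28.7 to 1021 CPM and Ubd, a ubiquitin-like modifier, from 7.65 to 261 CPM, with 13.3 and 3.89 CPM in WT without shared barcodes. The other genes among the 12 highest were Csmd1 (50.4-fold), Chl1 (33.5-fold), Hdac9 (29.6-fold), Pcdh15 (28.9-fold) and Cpxm1 (24.4-fold). Without shared barcodes these 5 ratios were 225, 60.4, 58.3, 59.3 and 38.9.

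Among the 12 lowest genes, Clec3b (chromosome 9, 123150946 to 123157432, plus strand), which encodes tetranectin, went from 1207 to 87.1 CPM, 13.9-fold lower (13.4 to 14.4). Fbln1 (chromosome 15, 85205949 to 85286535, plus strand), a basement membrane fibulin, went from 1579.9 to 130.2 CPM, 12.1-fold lower. The Wnt modulator Dkk2 (chromosome 3, 132085292 to 132180304, plus strand) went from 202 to 9.08 CPM, 22.2-fold lower (19.8 to 24.99). The retinoid genes Rbp4, a retinol carrier, and Lrat, which esterifies retinol, were 17.2-fold and 19.4-fold lower, and the neurotrophin gene Ntf3 was 17.6-fold lower. Nkain3 was 64.6-fold lower (44.0 to 99.0), Col6a5 18.6-fold, Pcsk6 16.4-fold and Ces1d 10.3-fold. Iglc1, an immunoglobulin constant gene, went from 436 to 42.7 CPM, a WT level at 3.60% of that in plasma cells and so not told apart from RNA of other cells.

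**Figure D3:**
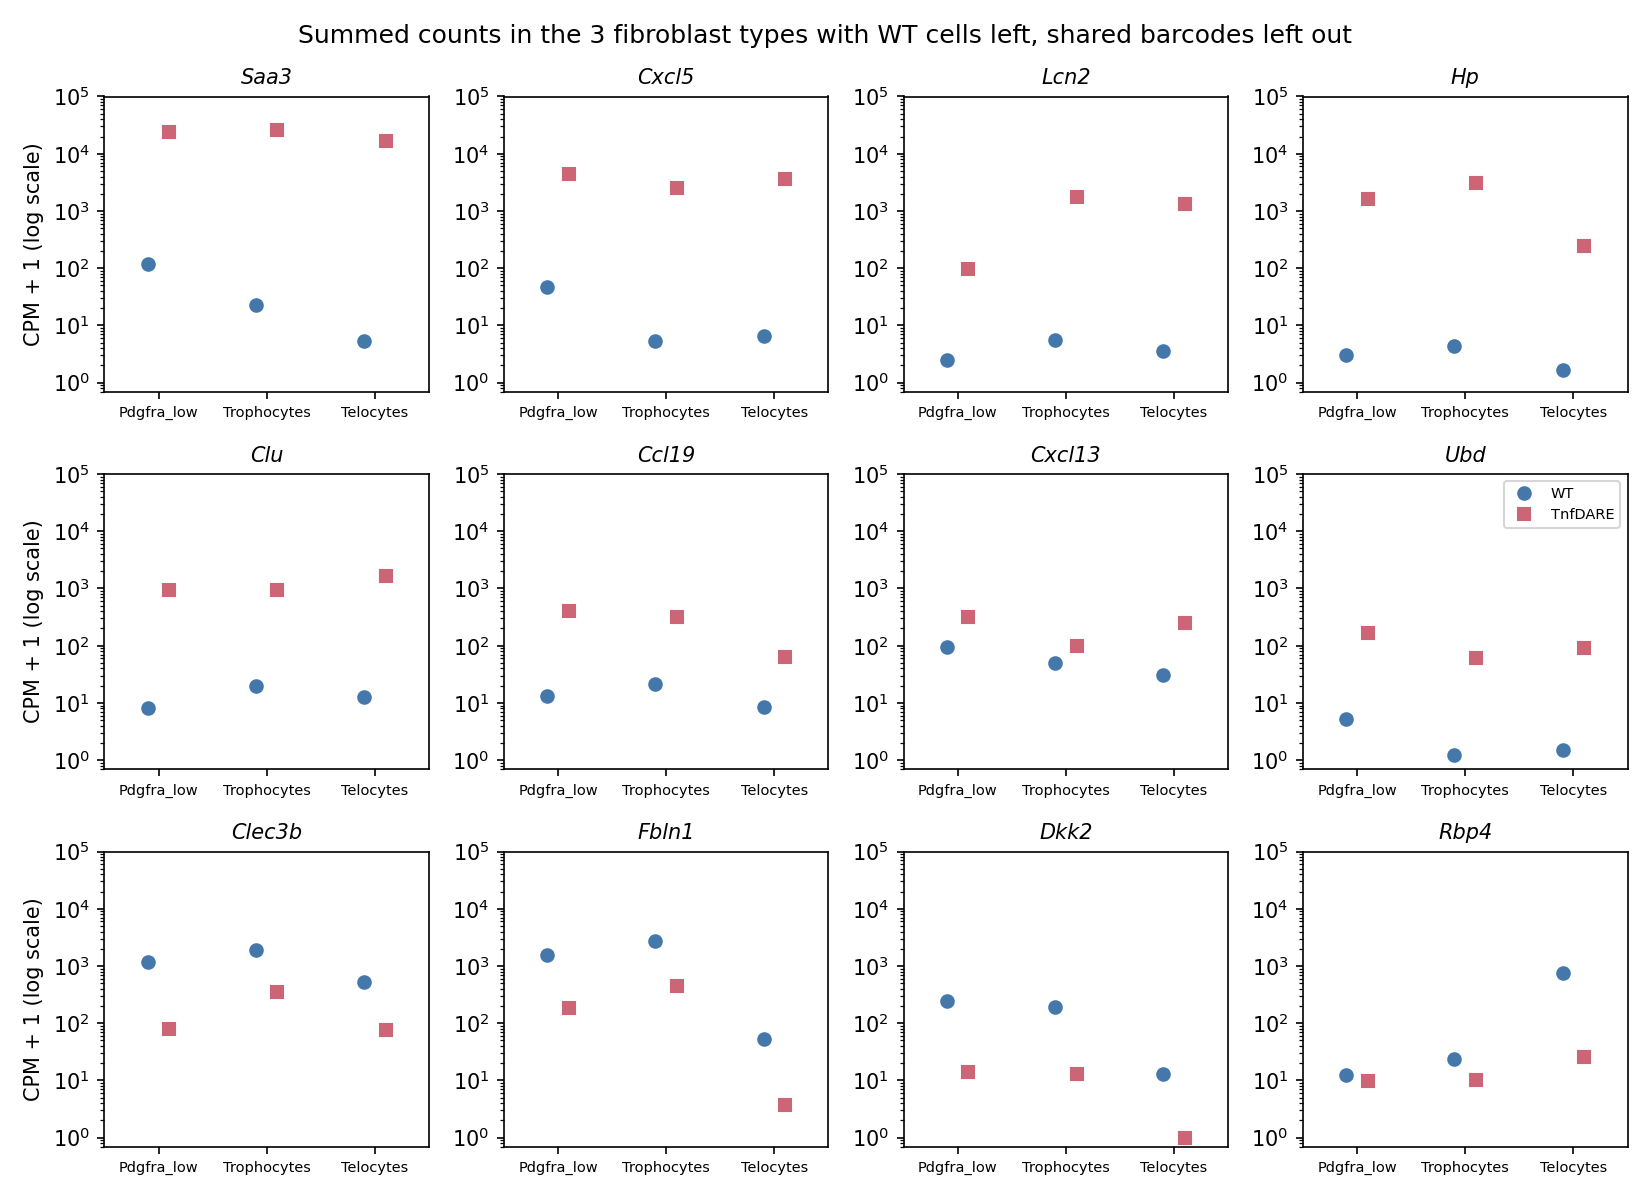
CPM plus 1 (log scale) of 12 genes in Pdgfra_low cells, trophocytes and telocytes of the WT library without shared barcodes and of the TnfDARE library, 1 library each. Saa3 was at 118 CPM in WT and 24042 CPM in TnfDARE Pdgfra_low cells.

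NF-kB and TNF target genes had 14 of 27 measured members at least 2-fold higher in TnfDARE fibroblasts and 0 lower, with a median log2 ratio of 0.91 at percentile 100 among 10000 random lists matched on CPM. Ccl2, a monocyte chemokine, went from 290.4 to 1744 CPM, Sod2, a mitochondrial superoxide dismutase, from 92.1 to 611 CPM, and the apoptosis inhibitor Birc2 from 58.8 to 288 CPM. Chemokines had 14 of 25 higher and 1 lower, among them Cxcl13, which guides B cells to follicles, at 139 CPM (82.1 without shared barcodes) and 2529.6 CPM, and Cxcl9 at 132 and 1580.2 CPM. Lymphoid tissue organiser genes had 13 of 17 higher (median 1.45), with Madcam1 at 3.07 (0.332 without shared barcodes) and 144 CPM and Tnfsf11, the cytokine RANKL, at 1.79 (0.743) and 76.5 CPM. FDCs_MRCs, with 0 WT cells left without shared barcodes, held 74949 of the 83263 TnfDARE fibroblast UMIs of Cxcl13, 2638 of the 4732 of Madcam1 and 1501 of the 2517 of Tnfsf11, while Cxcl13 went from 95.3 to 321 CPM within Pdgfra_low cells, from 49.9 to 96.3 CPM within trophocytes and from 29.8 to 251 CPM within telocytes. Inflammatory cytokines and acute mediators had 16 of 28 higher and 1 lower. The interferon gamma response had 9 of 23 higher (median 0.51; Gbp5 25.2 and 102 CPM), whereas the type I interferon response had 9 of 23 lower and 1 higher (median -0.41), with Isg15 at 42.0 and 6.56 CPM and Ifit3 at 53.5 and 12.8 CPM. MHC class I genes had 2 of 18 higher (H2-Q7, 359 and 1048 CPM) with a median of 0.72, and MHC class II genes 9 of 13, with Cd74 in TnfDARE at 709 CPM. TNF superfamily ligands and receptors had 7 of 21 higher (Tnfsf15, 2.73 and 19.7 CPM) and complement genes 4 of 14 (C3, 1336 and 8515 CPM). With equal weight for each cell type and shared barcodes left out, the higher members were 5 for NF-kB targets, 7 for organiser genes, 16 for inflammatory genes, 9 for chemokines, 1 for the interferon gamma response and 6 for MHC class II (2, 2, 6, 6, 0 and 0 with shared barcodes, where WT cells of FRC1, FRC2 and FDCs_MRCs are nearly all TnfDARE barcodes). Types needed 20 cells per library, so without shared barcodes FRC2, with 24 WT cells, weighed as much as Pdgfra_low cells, trophocytes or telocytes. FRC1 and FDCs_MRCs dropped out. Subtracting 90% of the pooled profile as free RNA, a ceiling and not a measured share, left 8, 4 and 8 higher members for NF-kB targets, inflammatory genes and chemokines.

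Collagens and matrix proteins had 12 of 32 members at least 2-fold lower and 1 higher (median -0.68, percentile 0), with Eln, elastin, at 467 and 79.7 CPM and Col14a1 at 899.8 and 199 CPM, and 10 lower with equal weight for each type and shared barcodes left out (7 with them). Matrix remodelling enzymes went both ways, 6 of 24 higher (Mmp3, 98.4 and 1455 CPM, and Timp1, 33.6 and 221 CPM) and 4 lower (Adamts1, 158 and 29.9 CPM). Epithelial niche factors had 11 of 31 lower, Wnt4 at 59.7 and 3.13 CPM and the Wnt antagonist Sfrp1 at 1046 and 245 CPM, and 6 higher, with the epithelial growth factor Fgf7 at 33.4 and 182 CPM (median -0.14, percentile 10.6). Telocyte genes had 5 of 10 lower and 1 higher, Sox6 at 343 and 69.0 CPM and Bmp4 at 429 and 137 CPM. Trophocyte genes had 4 of 9 lower, Ackr4 at 73.8 and 6.90 CPM, and 3 higher, the BMP blocker Grem1 at 521 and 1216 CPM. Retinoic acid and metabolic genes had 6 of 13 lower, Adh1 at 87.3 and 12.5 CPM, and 3 higher. Dissociation stress and immediate early genes had 20 of 23 lower (median -1.60), Egr1 at 3424 and 731 CPM and Ier2 at 788 and 163 CPM, and 18 lower with equal weight for each type and shared barcodes left out (10 with them).

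Within Pdgfra_low cells, trophocytes and telocytes, NF-kB and TNF target genes had 7, 14 and 20 of 27 members at least 2-fold higher, and chemokines 12 of 24, 13 of 22 and 11 of 22. In Pdgfra_low cells Hp was 818-fold higher (662 to 1022), Saa3 204-fold, Csmd1 175-fold, Clu 130-fold and Cxcl5 97.1-fold, while Lrat was 47.3-fold lower (29.1 to 82.8), Dkk2 18.4-fold, Clec3b 14.8-fold and Cd34 12.5-fold. Telocytes held 34 Saa3 UMIs in WT, 4.40 CPM, against 16544 CPM in TnfDARE, a ratio of 3759 (2689 to 5429). In telocytes Cxcl5 (650.2-fold), Lcn2 (514-fold), Clu (145-fold) and the complement gene C3 (118-fold) were also higher, and 12 of 13 complement genes were at least 2-fold higher. Telocyte genes had 7 of 9 members lower within telocytes (median -1.36), and Rbp4 went from 753 to 24.995 CPM there. Mgll was 56.5-fold lower (25.9 to 154) and Cav1 21.4-fold lower in telocytes, Meg3 went from 117 CPM to 0 UMIs (at least 70.2-fold lower by a floor of 3 counts), and Galnt15 had 2 UMIs in TnfDARE, a ratio of 0.0117 (0.00141 to 0.0423). In trophocytes Saa3 was 98.1-fold, Cxcl5 78.8-fold, Lcn2 74.2-fold, Hp 57.6-fold and Csmd1 44.6-fold higher, ratios that were 1220.2, 588, 394, 903 and 79.0 without shared barcodes. Angptl1 (20.5-fold), Dkk2 (15.8-fold), Lsamp (15.3-fold) and Iglc1 (13.5-fold) were among the lowest in trophocytes.

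Blood and lymphatic endothelium were compared for activation by TNF and interferon. Blood endothelial cells of TnfDARE had more of most interferon gamma response genes, of the adhesion genes Vcam1 and Sele, and of Ubd. Lymphatic endothelial cells had more of Adamts5, Mmp13, C3 and a part of the NF-kB targets, and less of some type I interferon genes such as Isg15. Both types had less Cyp26b1, which breaks down retinoic acid. Blood endothelium held 321 WT and 370 TnfDARE cells at median depths of 3937 and 8305.5 UMIs, and lymphatic endothelium 434 and 1219 cells at 5622.5 and 9473 UMIs. The mixture of blood endothelium changed: vein cells were 58 of its 321 WT cells (34 of 280 without shared barcodes) and 90 of its 370 TnfDARE cells.

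In blood endothelial cells Ubd (chromosome 17, 37193892 to 37196095, plus strand) was 11.6-fold higher (9.22 to 14.7; 39.1-fold without shared barcodes) and Cxcl9 11.4-fold (34.2 and 389 CPM; 28.3-fold without shared barcodes). D5Ertd615e was 10.4-fold and Fjx1 8.45-fold higher (23.7-fold and 23.3-fold without shared barcodes), and Syt1 had 2 WT UMIs, a ratio of 27.2 (7.37 to 227). The lowest genes included Hist1h2ap (142 CPM and 0 UMIs) and the genes Igkc, Iglc1, Adamdec1 and Defa21, which other cell types express. The histone gene Hist1h2ap was lower in all 10 classes, 1 of 15 genes that moved one way in every class, and 100% of the 50-mers at its transcript end also occurred in other genes' transcripts. The interferon gamma response had 16 of 24 members at least 2-fold higher (median 1.33), with the guanylate-binding Gbp3 at 35.7 and 141 CPM and Gbp2 at 90.4 and 323 CPM. Endothelial activation and leukocyte adhesion genes had 6 of 17 higher and 1 lower: Vcam1 went from 61.2 to 294 CPM and the leukocyte-rolling receptor Sele from 81.6 to 289 CPM. Madcam1, the gut homing address for lymphocytes, went from 215 to 634 CPM. Cyp26b1 went from 154 to 10.3 CPM, and cell cycle genes had 9 of 15 members lower. The free RNA share that plasma cell markers gave in blood endothelium was 19.2% in WT and 4.55% in TnfDARE.

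In lymphatic endothelial cells Adamts5 (chromosome 16, 85856173 to 85901828, minus strand), an aggrecan-cleaving protease, was 27.4-fold higher (19.4 to 40.1; 14.1 and 388 CPM; 65.7-fold without shared barcodes). C3 (60.1 and 1028 CPM, 17.1-fold), the desmosomal Dsg2 (33.3-fold) and the neurotensin gene Nts (11.03-fold) were also higher, Klrb1f had 2 WT UMIs, a ratio of 73.9 (20.4 to 611), and Saa3 stood at 0.767% of its fibroblast level, not told apart from RNA of other cells. Tppp3 went from 732 to 64.6 CPM, 11.3-fold lower. Matrix remodelling enzymes and inhibitors had 9 of 21 members higher and 4 lower, with the collagenase Mmp13 at 0.442 and 37.5 CPM and the plasminogen activator Plat at 18.6 and 123 CPM. NF-kB and TNF target genes had 13 of 27 higher and 0 lower (median 0.86; Vcam1 7.51 and 59.5 CPM, Ccl2 30.5 and 164 CPM), a count that was 8 with cells thinned to 1000 UMIs and 3 with 90% of the pooled profile subtracted as free RNA. Complement had 5 of 13 higher (Cfb, 12.4 and 146 CPM). The type I interferon response had 9 of 23 lower and 1 higher (median -0.72), with Isg15 at 144 and 20.1 CPM, and Cyp26b1 went from 197 to 18.1 CPM.

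Smooth muscle cells and pericytes, joined as a mural and muscle class of 785 WT and 372 TnfDARE cells at median depths of 7998 and 8220.5 UMIs, were compared for contractile and inflammatory genes. Many inflammatory, chemokine and interferon gamma genes were higher in TnfDARE mural cells, and some contractile genes lower. The class went from 667 smooth muscle cells and 118 pericytes in WT to 116 and 256 in TnfDARE, and summed smooth muscle markers went from 15793 to 9069.98 CPM and pericyte markers from 2032 to 6492 CPM. Saa3 was at 31.6 and 4474 CPM (142-fold, 124 to 163), the latter 17.6% of the fibroblast level. Cxcl5 was 37.2-fold, Hp 164-fold (78.9 to 409; 286-fold without shared barcodes), Clu 45.0-fold, Ccl19 24.6-fold and the metalloreductase Steap4 (chromosome 5, 7960457 to 7982213, plus strand) 32.0-fold higher. Clec3b was 55.3-fold, Fmo2 19.0-fold, Lsamp 13.7-fold and Hhip, a Hedgehog inhibitor of smooth muscle, 15.6-fold lower (812 and 52.1 CPM), and cardiac actin Actc1 had 3 UMIs in TnfDARE, a ratio of 0.00926. Contractile genes had 5 of 16 members at least 2-fold lower and 1 higher (median -0.82), with the muscle regulator Myocd at 267 and 61.8 CPM and smooth muscle myosin Myh11 at 1839.5 and 784 CPM. With equal weight for each type 2 contractile genes were lower, and 1 of 16 within SMCs and 4 of 16 within Pericytes. NF-kB targets had 13 of 27 higher and 2 lower (Ccl2, 89.9 and 1073 CPM), and the interferon gamma response 14 of 23 higher (Gbp5, 17.7 and 114 CPM). Angiogenesis genes had 6 of 14 higher and 1 lower, with placental growth factor Pgf at 17.1 and 98.4 CPM. Epithelial niche factors had 13 of 28 lower, with Ereg, an EGF receptor ligand, at 214 and 38.1 CPM. MHC class II genes had 11 of 12 higher, but 0 with cells thinned to 1000 UMIs.

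Macrophages and monocytes were compared for resident, recruited and inflammatory programmes. The cytokine genes Il6 and Lif and the hypoxia gene Vegfa were higher in the TnfDARE class, and Mrc1 and some other resident macrophage genes and Isg15 lower. The mixture of the class changed with them: activated macrophages were 258 of 1222 WT cells (9 of 652 without shared barcodes) and 868 of 2806 TnfDARE cells. It held 1222 WT cells at a median of 3840.5 UMIs (652 cells at 9114 UMIs without shared barcodes) and 2806 TnfDARE cells at 13662.5 UMIs. Il6 (chromosome 5, 30013114 to 30019981, plus strand) went from 14.2 to 101 CPM, 7.11-fold (10.3-fold without shared barcodes), and the related cytokine Lif (chromosome 11, 4257557 to 4272514, plus strand) from 15.8 to 113 CPM, 7.14-fold (10.8-fold without shared barcodes). Saa3 was 6.54-fold (38.5 without shared barcodes), Ly6i 6.20-fold (12.8), Tma16 5.44-fold (10.5) and Ccl5, a T cell chemokine, 5.12-fold higher (9.80 without shared barcodes). Gbp2b was 31.7-fold lower (217 and 6.86 CPM), the adhesion receptor Adgrl3 28.2-fold, Cadm1 13.1-fold and Apol7c 12.5-fold lower, and Igkc was also among the lowest.

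Inflammatory cytokines and acute mediators had 12 of 27 members at least 2-fold higher and 0 lower in macrophages and monocytes (15 higher without shared barcodes), among them Il12a at 2.48 (0.452 without shared barcodes) and 26.0 CPM, and 5 with equal weight for each type, 6 with thinned cells and 7 by the mean CPM per cell. Resident macrophage genes had 9 of 20 lower and 1 higher (median -0.68): the mannose receptor Mrc1 went from 144 to 35.5 CPM, Cd72 from 99.4 to 10.6 CPM and the phagocytic receptor Timd4 from 14.9 to 2.84 CPM. That count was 4 with thinned cells, by the mean CPM per cell and without cells over 3 times the median UMIs, and 5 with equal weight. These settings, also where used for the inflammatory list, kept the shared barcodes in WT, without which 652 of its 1222 cells were left. Leaving out cells over 3 times the median UMIs took out 157 WT and 2 TnfDARE cells of the class. For Resident_Mfs in WT that median was 2151 UMIs, against 14656.5 without shared barcodes and 1724 within them. WT cells that were not shared were thus the likelier to be taken out. The 4 under this cut therefore does not test the resident result. Without shared barcodes the median log2 ratio of resident genes was -0.75. Recruited monocyte genes went both ways, 3 of 15 higher (Ly6i, 60.8 and 377 CPM) and 4 lower (the Fc receptor Fcgr1, 74.9 and 13.5 CPM). Glycolysis and hypoxia genes had 8 of 20 higher (median 0.84), with Vegfa at 132 and 396 CPM and Tpi1 at 76.5 and 211 CPM. Equal weight for each type, which also kept the shared barcodes in WT, left 1. The type I interferon response had 13 of 23 lower and 1 higher (Isg15, 235 and 32.4 CPM). Chemokines had 10 of 25 lower and 6 higher: Ccl2 went from 182 to 25.7 CPM, the reverse of its direction in fibroblasts, and Ccl7 from 51.6 to 4.60 CPM.

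Dendritic cells were compared for maturation genes. Fscn1, Relb and Cd40 were higher in TnfDARE dendritic cells and the retinoic acid enzyme Aldh1a2 lower, in a class whose mixture changed: Cdc2_b went from 37 to 316 cells, Cdc1 from 263 to 133, and summed migratory dendritic cell markers from 212 to 826 CPM. The class held 825 WT and 962 TnfDARE cells at median depths of 13590.0 and 10383 UMIs. Fscn1 (chromosome 5, 142960343 to 142973185, plus strand), the actin bundler of mature dendritic cells, went from 13.7 to 282 CPM (20.5-fold, 17.5 to 24.3). Dpp10 was 86.8-fold (57.1 to 139), Syt1 90.1-fold (170.1-fold and 412-fold without shared barcodes), Tmem150c 70.3-fold and Dscaml1 50.3-fold higher, and Saa3 stood at 0.592% of its fibroblast level. St18 was 12.3-fold, Ctla2b 9.49-fold and the chemokine Ccl17 9.22-fold lower, with Iglc1 also among the lowest. Lymphoid tissue organiser genes had 9 of 16 members at least 2-fold higher and 1 lower, with the lymphocyte survival cytokine Il15 at 11.1 and 59.2 CPM and Relb, a subunit of non-canonical NF-kB, at 141 and 318 CPM. NF-kB targets had 7 of 27 higher (Cd40, 31.6 and 94.3 CPM), and 3 with equal weight for each type. Organiser genes had 2 of 11 higher within Cdc1 and 3 of 13 within Cdc2_a. Aldh1a2 went from 74.1 to 9.75 CPM.

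Granulocytes of the myeloid compartment, 181 in WT and 2496 in TnfDARE at median depths of 3040.0 and 3225.5 UMIs, were compared for chemokine and interferon genes. Ccl3 and some type I interferon genes were lower in TnfDARE, and some interferon gamma response genes higher. In this class summed neutrophil markers went from 26399.6 to 51298 CPM and plasma cell markers from 8783 to 1337 CPM, and the free RNA share that plasma markers gave was 17.03% in WT and 7.35% in TnfDARE. Flot1 was 4.20-fold higher (2.33 to 8.46), Rdh11 had 2 WT UMIs, a ratio of 8.14 (2.23 to 67.6), and Cxcl5, Clu, Lyz1 and Cp stood below 5% of the level in another class. Iglc1, Igkc, Iglc2 and Txndc5, which plasma cells express, were among the lowest. NF-kB targets had 0 of 27 members higher and 1 lower in granulocytes. The type I interferon response had 7 of 22 lower and 2 higher (Isg15, 494 and 182 CPM), and the interferon gamma response 5 of 23 higher and 1 lower (Gbp2, 232 and 566 CPM). Ccl3, a chemokine for monocytes and lymphocytes, went from 3067 to 1191 CPM.

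T and innate lymphoid cells were compared for effector and regulatory genes. Type 2 cytokine genes (Il4, Il13) were lower in the TnfDARE class, and genes of regulatory and naive T cells (Foxp3, Lag3, Lef1) higher, in a class where ILC2s had a smaller share and regulatory and naive CD4 T cells larger ones. It held 4838 WT and 2729 TnfDARE cells at median depths of 5763.5 and 5168 UMIs. Tff1 was 26.3-fold (21.2 to 33.0), the natural killer receptor gene Klra4 20.4-fold, Ttn 12.2-fold and Fabp5, a fatty acid carrier, 5.93-fold higher, while Saa3 and Hp were at a free RNA level. The neuropeptide gene Calca, which ILC2s express, was 12.6-fold lower (111 and 8.82 CPM), Hs3st1 12.1-fold, and Adamdec1 and Mzb1 were also among the lowest. T cell effector genes had 13 of 29 members at least 2-fold lower and 2 higher (median -0.86), with Il13 at 40.3 and 2.08 CPM, Il4 at 107 and 13.9 CPM and Il17f, higher, at 10.7 and 45.6 CPM. T cell activation and checkpoint genes had 6 of 21 higher and 2 lower, with the inhibitory receptor Lag3 at 5.69 and 41.1 CPM and the regulatory T cell factor Foxp3 at 13.3 and 48.2 CPM. Naive lymphocyte and recirculation genes had 6 of 14 higher (median 0.85), with S1pr1, the receptor by which lymphocytes leave lymphoid tissue, at 59.7 and 144 CPM and the T cell factor Lef1 at 204 and 445 CPM. With equal weight for each type these 3 lists had 6 lower, 2 higher and 1 higher members. The ILC2 gene Arg1 went from 40.8 to 4.28 CPM.

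B cells and plasma cells were compared for germinal centre and antibody class genes. Germinal centre genes differed little in B cells, and plasma cells of TnfDARE held more IgG and IgM constant-region RNA. The B class held 1450 WT and 4339 TnfDARE cells at median depths of 4061 and 4146 UMIs, and the plasma class 4775 and 1140 cells at 17767 and 18848.5 UMIs. In B cells germinal centre genes had 0 of 10 members 2-fold apart either way (median 0.20, percentile 99.4), with Rgs13 at 28.2 and 45.9 CPM. All 6 highest B cell genes (Saa3, Clu, Hp, Acod1, Cd14 and Lyz2) stood at 1.64% or less of the level in another class, and among the lowest were Adamdec1, Jchain, Fbln1 and Igha, which other types express. The activation marker Cd69 went from 442 to 259 CPM in B cells. In plasma cells Ighg3 (chromosome 12, 113356224 to 113361232, minus strand) went from 5.27 to 187 CPM (35.5-fold, 32.3 to 39.0), and the other IgG genes Ighg2c (13.2-fold), Ighg1 (9.45-fold) and Ighg2b (8.10-fold) and the IgM gene Ighm (6.49-fold) were also higher. Plasma cell and immunoglobulin constant genes had 5 of 19 members higher and 1 lower there (median 0.21). The same list was lower in 9 of 19 members in fibroblasts and in 11 of 17 in blood endothelium. In plasma cells rescaling by the median gene ratio shifted all log2 values by -0.16, and by under 0.1 in the other classes.

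**Figure D4:**
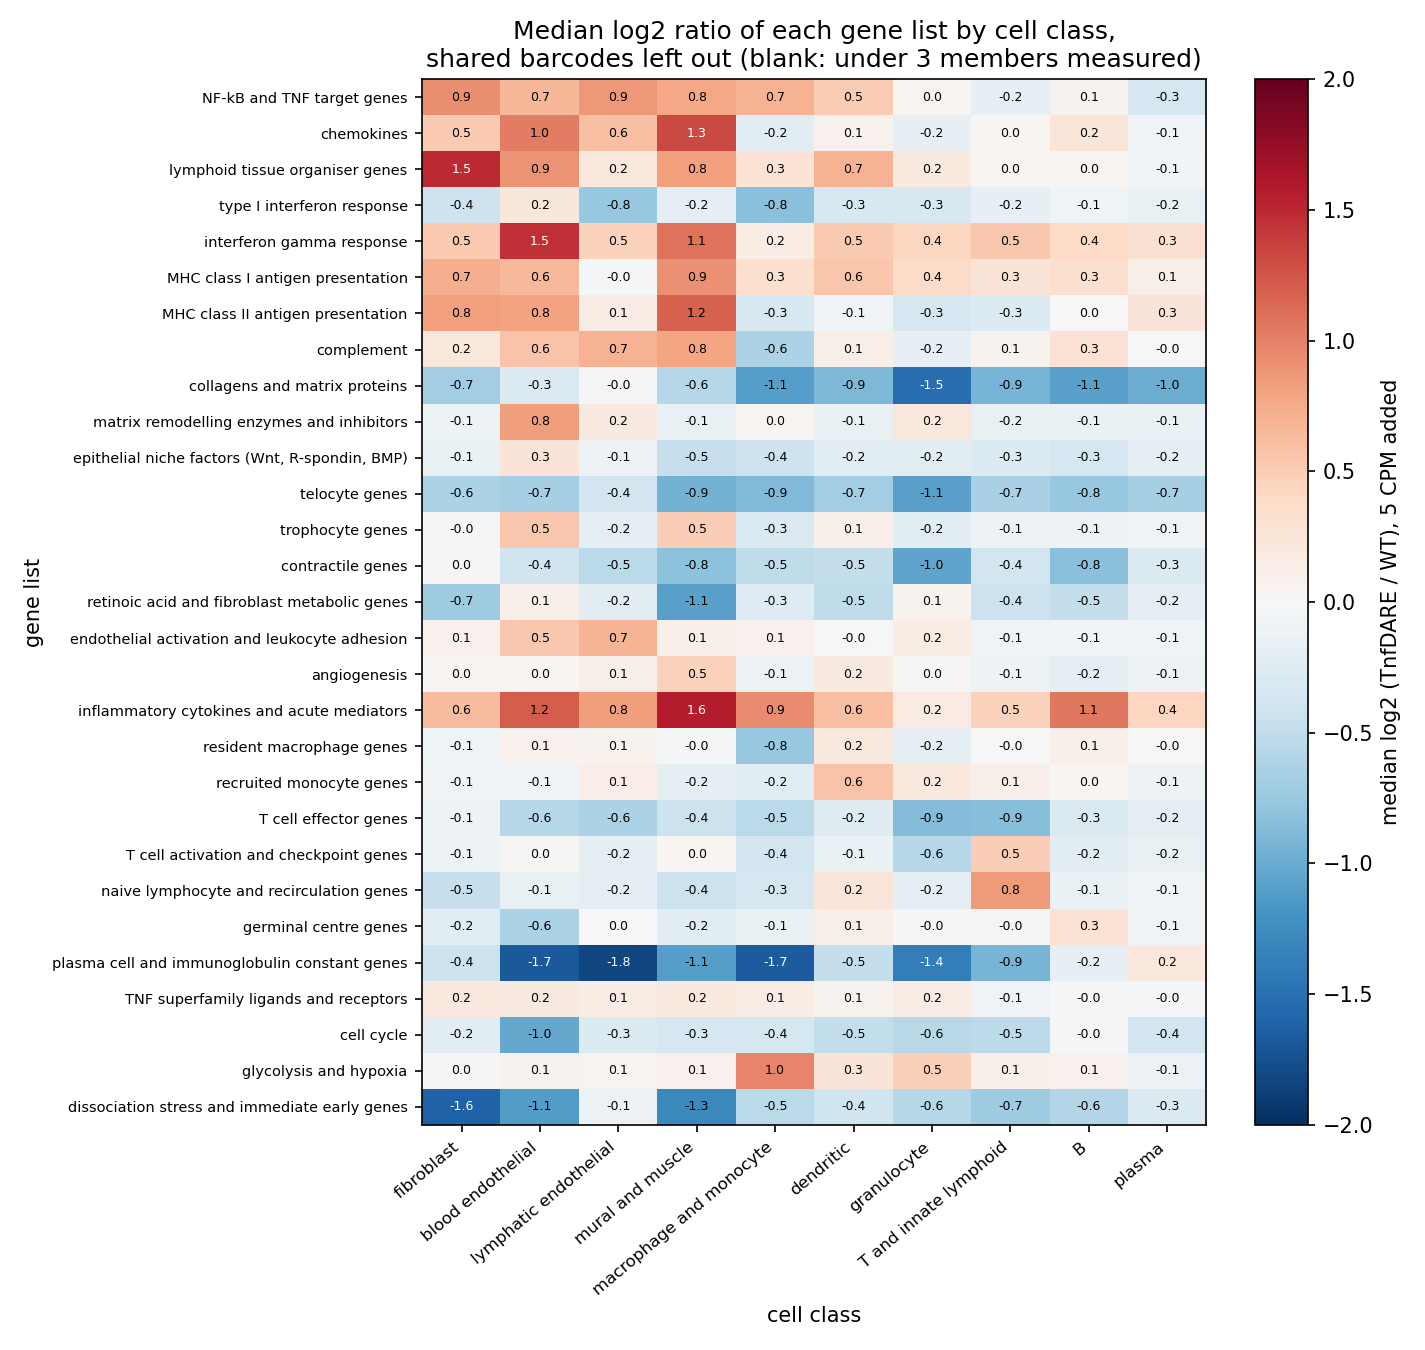
Median log2 ratio of TnfDARE over WT for each gene list and cell class, WT without shared barcodes, 1 library each. The interferon gamma response was positive in blood endothelium (1.46) and in T and innate lymphoid cells (0.53), and immediate early genes negative in fibroblasts (-1.61).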

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

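Some deposited data stood outside the annotation. Of the WT barcodes without an annotation, 10543 also occurred in the TnfDARE library with more UMIs there. Epithelial markers summed to 69.9 CPM in WT barcodes without annotation and 139 CPM in TnfDARE barcodes without annotation, against 45.0 and 34.8 CPM in annotated cells, although epithelium had been taken off and sorted away.

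Some lists moved in opposite directions in different classes, beside markers of other cell types that moved too, and whether these differences between classes exceeded chance was untested. Without shared barcodes, matrix remodelling enzymes and inhibitors had 6 members at least 2-fold higher in blood endothelial cells and 10 lower in plasma cells, where summed fibroblast markers went from 298 to 42.2 CPM. Angiogenesis genes had 6 members higher in mural and muscle cells and 6 lower in B cells, where summed fibroblast markers went from 473 to 109 CPM. Naive lymphocyte and recirculation genes had 6 members higher in T and innate lymphoid cells and 5 lower in lymphatic endothelial cells, where summed T cell markers went from 30.9 to 10.04 CPM and B cell markers from 42.7 to 15.3 CPM.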

How the results depend on the processing

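No paired analysis was possible because each genotype had 1 library and no animal or batch linked them. The causes of the moves below were not tested.

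Equal weight for each cell type, planned, moved higher members in fibroblasts from 14 to 2 for NF-kB targets, 13 to 2 for organiser genes, 16 to 6 for inflammatory genes, 14 to 6 for chemokines and 9 to 0 for the interferon gamma response. Lower members moved from 12 to 7 for collagens and 20 to 10 for immediate early genes in fibroblasts, and 13 to 6 for T cell effector genes. In macrophages the inflammatory list moved from 12 to 5 and resident genes from 9 to 5. The fibroblast and macrophage values kept the shared barcodes in WT. Among the equally weighted WT types these were 207 of 208 FRC1, 165 of 189 FRC2 and 119 of 119 FDCs_MRCs cells. They were also 249 of 258 Activated_Mfs and 251 of 421 Resident_Mfs cells. These fibroblast and macrophage moves therefore do not measure dependence on the weighting alone. With shared barcodes also left out, an added setting, the values were 5 for NF-kB targets, 7 for organiser genes, 9 for chemokines, 1 for the interferon gamma response and 6 for T cell effector genes. The fibroblast values there took Pdgfra_low cells, trophocytes, telocytes and FRC2, with 24 WT cells left, at equal weight.

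Subtracting free RNA at the largest marker share, an added setting that took its ceiling of 90% of the pooled profile in fibroblasts and lymphatic endothelium, left 8 NF-kB targets, 4 inflammatory genes and 8 chemokines in fibroblasts and 3 of 13 NF-kB targets in lymphatic endothelium, and 55 of 132 named genes changed sign. A second subtraction at the plasma cell marker share, chosen after the first result had been seen, left 13 NF-kB targets in fibroblasts, 18 of 132 named genes changing sign.

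Cells thinned to 1000 UMIs, planned, gave 8 NF-kB targets in lymphatic endothelium, 6 inflammatory and 4 resident genes in macrophages, and turned the ratio of macrophages with a Tnf UMI from 1.54 to 0.917. The mean CPM per cell gave 7 inflammatory and 4 resident genes, and leaving out cells over 3 times the median UMIs gave 4 resident genes. All of these macrophage values kept the shared barcodes in WT, without which 652 of 1222 WT cells were left. The medians behind the UMI cut were also taken with the shared barcodes kept, so that cut does not test the resident result.

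As shares of all annotated cells, planned, ratios moved from 0.216 to 0.124 for Pdgfra_low, 3.48 to 1.99 for FRC1, 4.85 to 2.78 for FRC2, 5.80 to 3.32 for lymphatic endothelium, 4.90 to 16.3 for granulocytes, 1.20 to 3.98 for activated macrophages, 4.28 to 3.76 for B cells and 0.322 to 0.282 for plasma cells. Resident macrophages turned from 0.408 to 1.36, the macrophage class from 0.817 to 2.71 and the dendritic class from 0.415 to 1.38. Marker-based classes, planned, turned the T and innate lymphoid share from 0.760 to 1.94. These classes equalled the annotated class for 81.6% of cells. Of cells annotated as T and innate lymphoid, 4440 kept that class and 3032 were placed with plasma cells. Immunoglobulin variable RNA in the annotated class was 275 CPM in WT and 30.7 CPM in TnfDARE. The turned ratio leaves out the cells placed with plasma cells.

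Added settings moved shares too. Without shared barcodes ratios were 667 for FRC1, 35.2 for FRC2, 3.47 for granulocytes, 23.6 for activated macrophages, and the macrophage class turned to 1.05. With TnfDARE cells that had Xist and no Y-linked UMI, Pdgfra_low was 0.246, granulocytes 3.44, activated macrophages 1.59, plasma cells 0.277, and the macrophage class turned to 1.03. With Y-linked UMIs and no Xist, granulocytes were 3.48, plasma cells 0.395, and Tnf in granulocytes moved from 0.587 to 0.513. Leaving out cells with 2 markers of another compartment left too few cells for values.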

Other observations

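Mesothelial cells had the highest Saa3 of any annotated type in the TnfDARE library, 82664 CPM against 22812 CPM in WT (6263 CPM without shared barcodes). Smooth muscle cells went from 33.8 to 9032 CPM and pericytes from 8.40 to 1395 CPM. FRC1 and FRC2 cells of the TnfDARE library, fibroblastic reticular cells, held 39251 and 28403 CPM. Among macrophage types Activated_Mfs went from 6629.7 (3159 without shared barcodes) to 8904 CPM, a ratio of 1.34 (2.82 without shared barcodes).

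The tests of chance sharing and of exchange in both directions were chosen after the shared barcodes had been seen, that of chance sharing with the Y-linked values already known. WT barcodes that also occurred in the TnfDARE library could be TnfDARE molecules counted in WT: 100% of 1126 cells annotated in both libraries were closer in profile to the TnfDARE barcode of equal sequence than to another TnfDARE cell of that annotation (99.7 to 100, median correlations 0.63 and 0.47). Cells of WT animals sharing a barcode by chance are argued against by Y-linked UMIs, in 22.0% of shared and 0.648% of other WT cells, a ratio of 34.0. Exchange both ways is argued against by a ratio of 0.00205 between the numbers for the 2 directions. At which step molecules crossed stays open.

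The tests of shared reads, of RNA from other cells as the whole cause and of chromosome 17 were chosen after 15 genes had been seen to move one way in all 10 classes. Reads shared between paralogs could play a part for some, since 26.7% (4 of 15) had most 50-mers of their last bases in another gene's transcripts, at percentile 99.4 among random sets (median 6.67, 95th percentile 20) and against 1.97% of 6187 genes. RNA from other cells could play a part for others, with a median ratio of 34.1 (quartiles over the genes 4.43 and 88.1) between the highest and lowest class in WT. Whether it was the whole cause cannot be told apart, since 5 genes stayed after subtraction at the plasma marker share and 0 after the largest share, which reached its ceiling of 90% in most classes. A haplotype linked to Tnf is argued against by 0 of the 15 genes on chromosome 17, with 10 chromosomes held, and other strain or annotation differences stay open and untested.

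The tests of a changed mixture and of the plasma marker share were chosen after the NF-kB result in fibroblasts had been seen. Sex of the animals as the cause of the 14 higher members is argued against by 13 with TnfDARE cells that had Xist and no Y-linked UMI. Subtraction at the largest marker share left 8, but took 90% of the pooled profile, a ceiling and not a measured share, so it neither excludes RNA from other cells nor gives grounds for it. Subtraction at the share that plasma cell markers gave, 7.23% in WT and 4.88% in TnfDARE, left 13 and argues against RNA from other cells at that share only. A changed mixture of fibroblast types as the whole cause is argued against by the smallest number within a type, 7 in Pdgfra_low cells. With equal weight for each type, however, 5 were left without shared barcodes (2 with them). The 5 gave FRC2, with 24 WT cells left, the same weight as Pdgfra_low cells, trophocytes or telocytes, and left out FRC1 and FDCs_MRCs. The part of a changed mixture in the 14 stays open. A response of fibroblasts to excess TNF, the difference named in the design, stays open as untested with 1 library per genotype.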
